A study of Mus musculus with 20 samples.

How the data were processed

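RNA from 20 cultures of mouse bone marrow-derived macrophages (DMSO, DSHN, GW3965 and both compounds, 5 biological replicates each) was sequenced after stranded mRNA library preparation with a Kapa kit, per the labels' protocols. Reads were aligned with STAR to the mouse genome GRCm39 with RefSeq annotation and counted per gene with featureCounts v2.0.0, per the file headers. The deposited values are raw read counts per gene, 1 file per library, with no normalization. No option for strand, multi-mapped reads, reads over several genes or read pairs stands in the commands of the file headers, so reads of either strand were counted.

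The files hold 46318 genes by NCBI GeneID, of which 44749 were named from a RefSeq table and 1569, with 0.474% of the counts, were not. No count was changed. Library totals of 16855029 to 23796561 counts set the depth, and 19208 genes had no count in any library. Replicates varied beyond counting error, with a biological coefficient of variation of 0.0536 and a chi-square per degree of freedom of 2.374 to 12.283 over 40 pairs of replicates. The labels give no batch. Libraries were treated as unpaired, with a replicate block as an alternative.

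Genes were kept by edgeR's filterByExpr (13307), scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood, with 1 mean per treatment over all 20 libraries. The 6 contrasts were each treatment against DMSO, the combination against each compound, and the interaction, which is the DSHN effect with GW3965 minus that without. P values were adjusted by Benjamini and Hochberg within each contrast and genes called under 0.05. CPM values use TMM factors, and log2 CPM for the principal components and slopes used a prior count of 2.

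There were 30 gene lists, 19 of pathways and 11 of cell markers and RNA quality, all written before the data were examined. Of 490 entries 481 were matched. The 26 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, voom values), with an estimated correlation and fry as alternatives. The neutrophil, T and NK cell, erythroid and RNA quality lists had fewer and were not tested. Named genes followed a rule fixed before the data were examined: per contrast the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in a compared group, and for pairwise contrasts no overlap of the 5 and 5 libraries (a separation that chance gives with an exact permutation p of 0.00794). Added to these were up to 4 members per pathway list with the smallest adjusted p, and always Nr0b2, Nr1h2, Nr1h3, Abca1, Abcg1, Srebf1 and Mylip. Unnamed gene models were skipped. Genes named beside these were chosen after their values were seen and are so described.

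Alternatives were DESeq2 size factors, total counts only, no filter, a stricter filter (1 CPM in 5 libraries and 100 counts), DESeq2 1.42.0, limma voom, only the groups of the contrast, glmTreat against a fold of 1.5, a replicate block and leaving out each library. A length correction was added after a trend with gene length was seen: per-library offsets from a spline with 5 degrees of freedom on log2 exon length, and a version that added genomic span and GC content. Exon lengths and coordinates are those of the files. Transcript length and GC content came from GENCODE annotation of GRCm38, matched by name for 12738 tested genes (95.72%), and no coordinate of that build is given. Correlations of effects ran across genes, with a jackknife over libraries for their error. Differences of library measures were tested by two-sided exact permutation.

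The gene test was tested on simulated counts for DSHN against DMSO (13097 genes): it recovered 29 of 50 genes changed 1.25-fold, 43 of 50 at 1.5-fold, 45 of 50 at 2-fold and 50 of 50 at 4-fold, and called 12 unchanged genes. With a length trend simulated for the combination against GW3965 (13086 genes), 4042 unchanged genes were called without the correction and 11 with it, and 137 of 150 changed genes were recovered. The simulated trend was a straight line on log2 exon length, the measure that the correction uses. The result therefore does not cover a trend with genomic span or GC content. Of 25 simulated lists the shifted one was called and no other. Genes were drawn independently of each other there, so lists of correlated genes were not tested.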

Results

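RNA was sequenced from bone marrow-derived macrophages of C57BL/6 female mice, grown with recombinant M-CSF, the growth factor that turns marrow progenitors into macrophages. The cells were kept for 24 h with 1 of 4 treatments, with 5 biological replicates of each and 20 libraries in all. The treatments were DMSO (the solvent), DSHN at 50 µM, GW3965 at 1 µM, and both compounds at these doses. Per the labels, GW3965 is an agonist of LXR, the oxysterol receptor that controls cholesterol export, and DSHN is an agonist of NR0B2, a nuclear receptor that the series describes as an inhibitor of LXR. The values are read counts per gene. Library totals ran from 16855029 to 23796561 counts. Group means were 20280000 ± 1682000 counts (SD, n = 5) with DMSO, 20680000 ± 2434000 with DSHN, 20620000 ± 1325000 with GW3965 and 18280000 ± 1783000 with both. Of 46318 genes in the files, 13307 had enough counts to be tested. Coordinates are those of the files (GRCm39), and levels are given as CPM, read counts scaled to a common library size with TMM factors, as mean ± SD of 5 libraries. Fold changes are on the log2 scale with their standard errors (SE). The first principal component (37.59% of the variance) set the combination libraries apart from the other 15, and the second (19.76%) ran from DMSO to GW3965 libraries. Position on the first component also went with the slope of each library's counts on exon length, described below. It therefore does not tell the treatment from that trend.

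**Figure D1:**
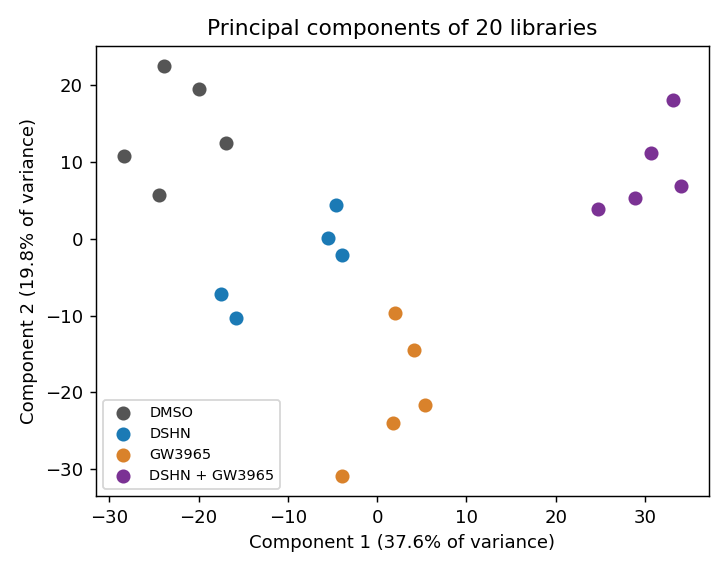
Each point is 1 of the 20 libraries, placed by the first and second principal components of log2 CPM (axes without unit, with the share of variance of each). The groups occupy separate areas, with 37.59% of the variance on the first axis and 19.76% on the second. DSHN replicates 4 and 5 (−15.81 and −17.47 on the first axis) lie apart from DSHN replicates 1 to 3 (−5.55 to −3.95). Their slopes of counts on exon length, described below, were 0.055 and 0.063 in replicates 4 and 5 and 0.0057 to 0.0253 in replicates 1 to 3. On the second axis replicates 4 and 5 lie apart from replicates 1 to 3 in every group. They are lower with DSHN (−10.34 and −7.2 against −2.17 to 4.32) and higher in the other groups (with DMSO 19.42 and 22.41 against 5.7 to 12.5).

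The receptor named in the study's rationale was barely transcribed. Nr0b2 (GeneID 23957, chromosome 4, 133280687 to 133283997) had 3 to 8 counts per library with DMSO, 0 to 3 with DSHN, 0 to 4 with GW3965 and 2 to 7 with both, so it fell below the filter of the gene test. An exact two-sided permutation test of its CPM (scaled by library totals), chosen after the counts were seen, gave 0.223 ± 0.0872 with DMSO against 0.0788 ± 0.05558 with DSHN (p = 0.00794, the smallest that 5 against 5 can give, adjusted p = 0.0397 over 5 comparisons). GW3965 against DMSO had an exact adjusted p of 0.0662 and the combination 0.841. Fitted by edgeR without the filter, DSHN against DMSO had adjusted p = 0.129 and the interaction was 2.31 (SE 0.88, adjusted p = 0.04). The genes of the LXR proteins themselves were expressed. Nr1h2, which encodes LXR beta, had 51.59 CPM ± 1.725 with DMSO, and Nr1h3, which encodes LXR alpha, had 14.38 CPM ± 0.9036. With DSHN alone Nr1h3 was lower by a log2 change of −0.25 (SE 0.07, adjusted p = 0.011) and Nr1h2 higher by 0.14 (SE 0.04, adjusted p = 0.00927). With GW3965 alone Nr1h3 had a log2 fold change of −0.005 (SE 0.07, adjusted p = 0.96). Against DSHN alone, Nr1h3 was higher in the combination by 0.35 (SE 0.08, adjusted p = 0.000246).

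The comparison of DSHN with DMSO asks what the NR0B2 agonist does alone. The genes with the largest rises were Ednrb, an endothelin receptor, which went from 22.91 CPM ± 3.935 to 70.48 CPM ± 8.309 (log2 fold change 1.61, SE 0.12), Dbp, a clock-controlled transcription factor (1.34), Ms4a4a (1.30), Nat8l (1.19), the costimulatory receptor gene Cd28 (1.13) and the iron exporter gene Slc40a1 (1.02). The largest falls were in Serpinb2, an inhibitor of plasminogen activators (−2.26), Fos, an immediate early transcription factor (−1.94), the monocyte chemokine genes Ccl7 (−1.87) and Ccl2 (−1.57), Ptgs2, which encodes cyclooxygenase 2 (−1.50), and Nptx1 (−1.47). Of 20 NRF2 target genes, which serve glutathione synthesis and the defence against oxidants, 15 rose and none fell (the same adjusted over the list alone), among them Gclm (0.53, SE 0.04), Blvrb (0.49), Gstm1 (0.61) and Gsta3 (1.01, SE 0.10). Of 16 LXR target genes 10 rose and 2 fell (12 and 2 adjusted over the list alone). Apoe, the lipoprotein that carries exported cholesterol, rose by 0.68, Cd5l by 0.58 and the sterol exporter gene Abca1 by 0.46 (SE 0.12), while Lpl, which encodes lipoprotein lipase, fell by 0.96 (SE 0.04) from 5341 to 2737 CPM. Abca1 in DSHN replicates 1 and 2 (208.8 and 236.5 CPM) lay within the DMSO range of 156.6 to 264.1 CPM, and the call was kept without any 1 library (adjusted p up to 0.0253). Replicates 4 and 5 had 346.2 and 345.3 CPM with DSHN and 172.8 and 156.6 CPM with DMSO. Replicates 1 to 3 had 208.8 to 294.7 CPM with DSHN and 219 to 264.1 CPM with DMSO. The rise thus lay mainly in replicates 4 and 5, which leaving out 1 library cannot show. Srebf1, the lipogenic transcription factor that LXR induces, had a log2 fold change of −0.03 (SE 0.05, adjusted p = 0.69). Abcg1 was higher by 0.29 (SE 0.10, adjusted p = 0.0284), a call lost without DMSO replicate 1, 4 or 5 or DSHN replicate 3, 4 or 5, with adjusted p up to 0.104. Of 14 inflammatory cytokine and enzyme genes 6 fell and none rose (the same adjusted over the list alone), with Tnf at −1.02 beside Ptgs2, Ccl2 and Ccl7.

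Across 13307 genes, DSHN changed 3852 by edgeR's quasi-likelihood test, 1880 higher and 1972 lower (1579 and 2246 scaled by total counts alone). Of the 3852, 36 were over 2-fold higher and 47 over 2-fold lower. By limma's camera, 10 of 26 lists moved relative to the other genes. Only NRF2 targets also passed with an estimated correlation (adjusted p = 3.56e-12, and 0.000923 with an estimated correlation). LXR targets moved up (adjusted p = 0.000171, and adjusted p = 0.385 with an estimated correlation). Inflammatory genes moved down (0.00579, and adjusted p = 0.385 with an estimated correlation). Lysosome and lipid-laden macrophage genes moved up with 16 of 25 higher and 3 lower (16 and 4 adjusted over the list alone), among them Lamp1 (0.35) and Tfec (0.61) against Spp1 (−0.96), at 0.000171 (adjusted p = 0.385 with an estimated correlation). Cell cycle genes moved down with 12 of 25 lower and 1 higher, among them the replication genes Pcna (−0.40) and Mcm5 (−0.42), at 0.000305 (adjusted p = 0.479 with an estimated correlation). Heat shock genes moved down with 7 of 13 lower (8 adjusted over the list alone), among them Hspb1 (−0.47), at 0.00138 (adjusted p = 0.201 with an estimated correlation). Glycolysis and hypoxia genes moved down with 9 of 22 lower and 3 higher (11 and 3 adjusted over the list alone), among them the glucose transporter gene Slc2a1 (−0.40), at 0.00612 (adjusted p = 0.526 with an estimated correlation). Antigen presentation genes moved up with 7 of 16 higher and 1 lower (9 and 2 adjusted over the list alone), among them H2-Aa (0.64), at 0.00808 (adjusted p = 0.479 with an estimated correlation). Nuclear receptor genes moved up with 9 of 16 higher and 2 lower, among them Nr1d2 (0.61) and Rxra (0.35) against Nr4a1 (−0.89), at 0.00808 (adjusted p = 0.201 with an estimated correlation). All 4 tested aryl hydrocarbon receptor targets passed, among them Ahrr (0.42), at 0.00345 (adjusted p = 0.0704 with an estimated correlation). Cholesterol synthesis genes were not called as a list, with 1 of 25 higher and 4 lower (adjusted p = 0.506), and fatty acid synthesis genes had 4 of 17 higher and 2 lower (4 and 4 adjusted over the list alone, 0.972). The counts not given adjusted over the list alone were the same there.

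GW3965 against DMSO shows the LXR agonist response. The largest rise was in the fatty acid desaturase gene Scd1 (GeneID 20249, chromosome 19, 44382889 to 44396148), from 12.92 CPM ± 1.477 to 267.6 CPM ± 9.048 (log2 fold change 4.37, SE 0.08). Next came Lbp, which encodes the lipopolysaccharide-binding protein (4.22), and the desaturase gene Scd2 (4.09, SE 0.08). Of the sterol exporter genes, Abcg1 (GeneID 11307, chromosome 17, 31276668 to 31336958) rose from 78.79 CPM ± 15.94 to 1287 CPM ± 107.3 (4.03, SE 0.10) and Abca1 (GeneID 11303, chromosome 4, 53030789 to 53159988) from 208.4 CPM ± 43.66 to 3150 CPM ± 328.5 (3.92, SE 0.13). The NAD-consuming ectoenzyme gene Cd38 rose by 3.76. Of 16 LXR targets 15 rose and none fell, including Srebf1 (2.32, SE 0.05), Mylip, which encodes a ubiquitin ligase (2.56, SE 0.07), and Lpcat3 (1.72). Fatty acid synthesis genes rose in 16 of 17 cases, with Fads2 at 2.56 and Acsl3 at 1.77. Cholesterol synthesis and uptake genes rose in 23 of 25, with Insig1 at 1.16 and Fdps at 0.95. The largest falls were again in Serpinb2 (−2.74), Fos (−2.50), Nptx1 (−2.29) and Ccl2 (−2.18), then in Rgs1 (−2.09) and the chemokine receptor gene Ccr3 (−2.01). Tnf fell by 1.98 and Cxcl2 by 1.89, while the cytokine gene Il1a rose by 2.70 from 0.8098 CPM ± 0.283. Arg1, which encodes arginase 1, had a log2 fold change of −3.09 from only 1.062 CPM ± 0.1903 with DMSO. Cell cycle genes were lower in 24 of 25 cases and higher in none, with Mcm4 at −0.78 and Mcm5 at −0.75.

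GW3965 changed 6194 genes, 3136 higher and 3058 lower, with 148 over 2-fold higher and 158 over 2-fold lower. Scaled by total counts alone, 2267 were higher and 4000 lower. The counts of the LXR, fatty acid, cholesterol and cell cycle lists were the same adjusted over the list alone. Of 11 lists called by camera, 3 also passed with an estimated correlation: LXR targets (adjusted p = 1.21e-20, median log2 fold change 1.74, and 0.00715 with an estimated correlation), fatty acid synthesis (3.44e-16, median 0.86, and 0.000181) and cholesterol synthesis and uptake (1.45e-15, median 0.51, and 0.000912). Cell cycle genes (2.75e-14) had adjusted p = 0.114 with an estimated correlation. Lysosome and lipid-laden macrophage genes were higher in 19 of 25 and lower in 4, with Hexa at 0.62 and Ctsb at 0.57 against Spp1 at −1.30 and Ctsl at −0.90 (2.42e-05, and adjusted p = 0.311 with an estimated correlation). Glycolysis and hypoxia genes were lower in 16 of 22 and higher in 3 (17 and 3 adjusted over the list alone), with Slc2a1 at −0.64 and Pkm at −0.33 (7.25e-05, and adjusted p = 0.311 with an estimated correlation). Antigen presentation genes were higher in 12 of 16 and lower in 1, with H2-Aa at 0.88 and Cd86 at 0.61 (0.00238, and adjusted p = 0.311 with an estimated correlation). PPAR targets were higher in 11 of 18 and lower in 1 (12 and 1 adjusted over the list alone), with Fabp5 at 0.97 and Pdk4 at 0.66 (0.00347, and adjusted p = 0.156 with an estimated correlation). Inflammatory genes were lower in 8 of 14 and higher in 1 (9 and 1 adjusted over the list alone, 0.0118, and adjusted p = 0.311 with an estimated correlation). Nuclear receptor genes were higher in 9 of 16 and lower in 2, with Rara at 0.64 (0.0132, and adjusted p = 0.156 with an estimated correlation). NRF2 targets were split, 7 higher and 8 lower of 20, with Nqo1 at −0.49 and Osgin1 at 0.85 (adjusted p = 0.837).

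**Figure D2:**
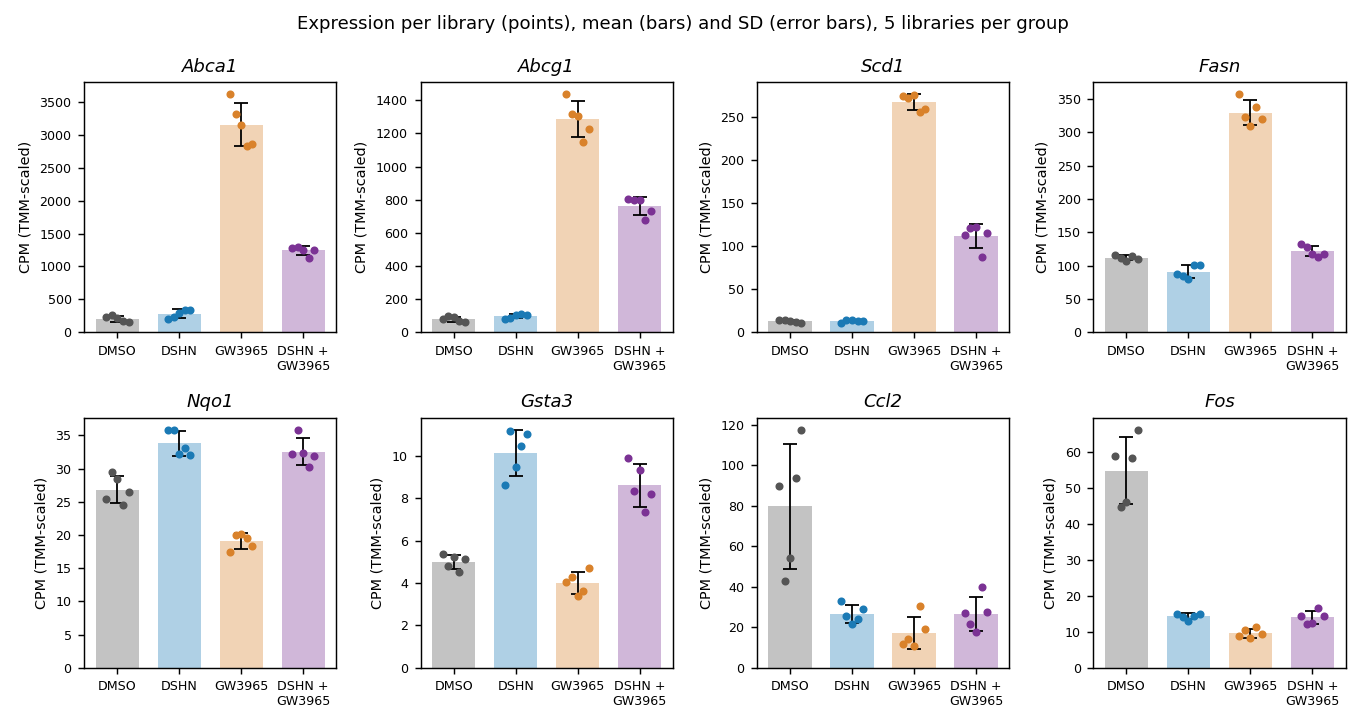
CPM of 8 genes (vertical axes, from 0) in the 4 treatment groups, with 1 point per library, bars at the mean and error bars of 1 SD of 5 libraries. Abca1 stood at 3150 CPM with GW3965 and 1244 CPM with both compounds, while Gsta3 stood at 4.007 CPM with GW3965 and 8.612 CPM with both.

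In the combination against DMSO, Scd2 was higher by 3.45 (SE 0.08), Abcg1 by 3.27 (SE 0.10), Scd1 by 3.11, Cd38 by 2.95, Abca1 by 2.58 (SE 0.13) and Il18bp, which encodes a decoy for interleukin 18, by 2.53. The largest falls were in Serpinb2 (−2.84), Xylt1, a xylosyltransferase of proteoglycan synthesis (−2.23), Ptgs2 (−2.14), Nptx1 (−2.13), Fos (−1.97) and Dhrs9 (−1.95). LXR targets were higher in 14 of 16 and lower in none, including Srebf1 (1.74), Mylip (2.31) and Arl4c (1.27). Fatty acid synthesis genes were higher in 11 of 17 and lower in 1 (12 and 2 adjusted over the list alone), with Fads2 at 2.11 and Acsl3 at 1.41. Cholesterol genes were higher in 22 of 25 and lower in 1, with Fdps at 1.11 and Insig1 at 0.99. NRF2 targets were higher in 14 of 20 and lower in 2 (15 and 2 adjusted over the list alone), with Blvrb at 0.78, Gstm1 at 0.78 and Gclm at 0.60. Cell cycle genes were lower in 18 of 25 and higher in 2, with Mki67 at −0.67 and Top2a at −0.64. Of 15 apoptosis and p53 targets 9 were higher and 3 lower, with Gadd45a at 1.04 and Bbc3 at 1.05, though the list was not called (adjusted p = 0.0609).

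The combination changed 8629 genes, 4248 higher and 4381 lower, with 248 over 2-fold higher and 342 over 2-fold lower. In these 5 libraries counts fell with the summed length of the gene's exons, relative to the mean of all 20 libraries. The slope on log2 exon length was taken from log2 CPM less each gene's mean over the 20 libraries. It was −0.124 to −0.0943 per library, against 0.0057 to 0.063 in the other 15. Slopes so centred balance out over the 20 libraries, so the positive values show no opposite trend of their own. The two-sided exact permutation p was 0.00794 against each group, the smallest that 5 against 5 can give. Adjusted over these 3 comparisons it stays 0.00794. The share of counts on mitochondrial rRNA and tRNA features was 0.2318% ± 0.0197 in the combination and 0.1233% ± 0.009664 with DMSO. With the length trend taken out per library, a correction chosen after the trend was seen, 7770 genes were called, and 6213 (72%) of the 8629 kept their call and sign, while 164 were called with the opposite sign. Of 9 lists called by camera, 3 passed with an estimated correlation: cholesterol (1.98e-08, and 0.0336), fatty acid synthesis (0.000134, and 0.0448) and NRF2 targets (0.000135, and 0.0448). With the length correction NRF2 targets had 0.00412 and lost the pass with an estimated correlation (adjusted p = 0.051), and their median log2 fold change went from 0.36 to 0.17. LXR targets had 9.02e-11 (adjusted p = 0.06 with an estimated correlation) and cell cycle genes 0.000135 (adjusted p = 0.508 with an estimated correlation). Lysosome genes, 15 of 25 higher and 5 lower, had 0.00654 (adjusted p = 0.577 with an estimated correlation). Antigen presentation genes were higher in 13 of 16, with Cd74 at 0.53, at 0.00118 (adjusted p = 0.393 with an estimated correlation), and the length correction ended this call (0.103). The same correction ended the calls of the integrated stress and unfolded protein response (12 of 22 higher, 3 lower, 13 and 3 adjusted over the list alone, Atf4 at 0.64; 0.0269 before and 0.535 after) and of PPAR targets (12 of 18 higher, 3 lower, Fabp5 at 0.92; 0.0269 before and 0.285 after). Both lists had adjusted p = 0.393 with an estimated correlation. Inflammatory genes, with 6 of 14 lower and 2 higher, were called with the length correction and not without it (0.323 before and 0.0289 after, adjusted p = 0.629 with an estimated correlation), with 9 lower, 1 higher and a median going from −0.60 to −0.92.

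The combination against GW3965 alone asks whether DSHN changes the LXR agonist response. LXR targets were lower in 11 of 16 and higher in 1, at a median of −0.32. Abca1 dropped from 3150 CPM ± 328.5 to 1244 CPM ± 65.75 (log2 fold change −1.34, SE 0.12), Abcg1 from 1287 CPM ± 107.3 to 762.5 CPM ± 55.81 (−0.75, SE 0.09), and Cd5l had −0.73, Srebf1 −0.58 (SE 0.05), Lpcat3 −0.52 and Mylip −0.25 (SE 0.06). Fatty acid synthesis genes were lower in 10 of 17 and higher in 1. Fasn, the fatty acid synthase gene (GeneID 14104, chromosome 11, 120696784 to 120715992), went from 329.8 CPM ± 18.24 to 122 CPM ± 7.917 (−1.43, SE 0.06), close to its 111.8 CPM ± 3.587 with DMSO. Scd1 had −1.25 (SE 0.07), Acaca, which makes malonyl-CoA, −1.01 and the citrate lyase gene Acly −0.55. Cholesterol genes were split, 7 higher and 7 lower of 25 (adjusted p = 0.746). NRF2 targets were higher in 16 of 20 and lower in 2, with Nqo1 at 0.77, Gclm at 0.61, Prdx1 at 0.59 and Txn1 at 0.58. The largest rises were in Gsta3 (1.11, SE 0.10), the nuclear RNA Neat1 (1.06), Klra2 (0.98), Afp (0.96), the neuropeptide Y gene Npy (0.93) and Snhg5 (0.93), and Arg1 was higher by 2.23, at 0.5822 CPM ± 0.1652 in the combination. The largest falls were in the matrix genes Svep1 (−1.83), Col12a1 (−1.70) and Fbn1 (−1.53), the deubiquitinase gene Usp9x (−1.60), Zbed6 (−1.58) and Elk4 (−1.56). These falls are given before the length correction, and the longest decile of exon length had a median of −0.272 in this comparison.

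In this comparison 7688 genes changed, 3760 higher and 3928 lower, with 74 over 2-fold higher and 160 over 2-fold lower (77 and 105 with the length correction). Scaled by total counts alone, 4637 were higher and 3295 lower. With the length correction 6289 were called, and 4812 (62.59%) of the 7688 kept call and sign, while 179 were called with the opposite sign. NRF2 targets (1.37e-05, and 0.0364 with an estimated correlation) and LXR targets (0.00275) stayed past the threshold after the correction, at 0.000192 and 4.96e-05. The LXR call was lost with an estimated correlation, with adjusted p = 0.912 before and adjusted p = 0.614 after the length correction. The NRF2 median went from 0.37 to 0.18 and its higher members from 16 to 12, while the LXR median was −0.32 before and after. Fatty acid synthesis had 0.000942 (adjusted p = 0.0994 with an estimated correlation), and 4.96e-05 after the length correction (adjusted p = 0.0342 with an estimated correlation). Stromal cell markers were lower in all 9 tested genes (0.00275, and adjusted p = 0.912 with an estimated correlation; 0.00239 after the length correction, with 7 lower and a median going from −0.40 to −0.28). The counts of these 4 lists were the same adjusted over the list alone. The calls on Gsta3, Neat1, Nqo1, Gclm, Abca1, Abcg1, Srebf1, Mylip, Fasn, Scd1 and Acaca remained after the length correction, with Abca1 at −1.08 and Fasn at −1.17.

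**Figure D3:**
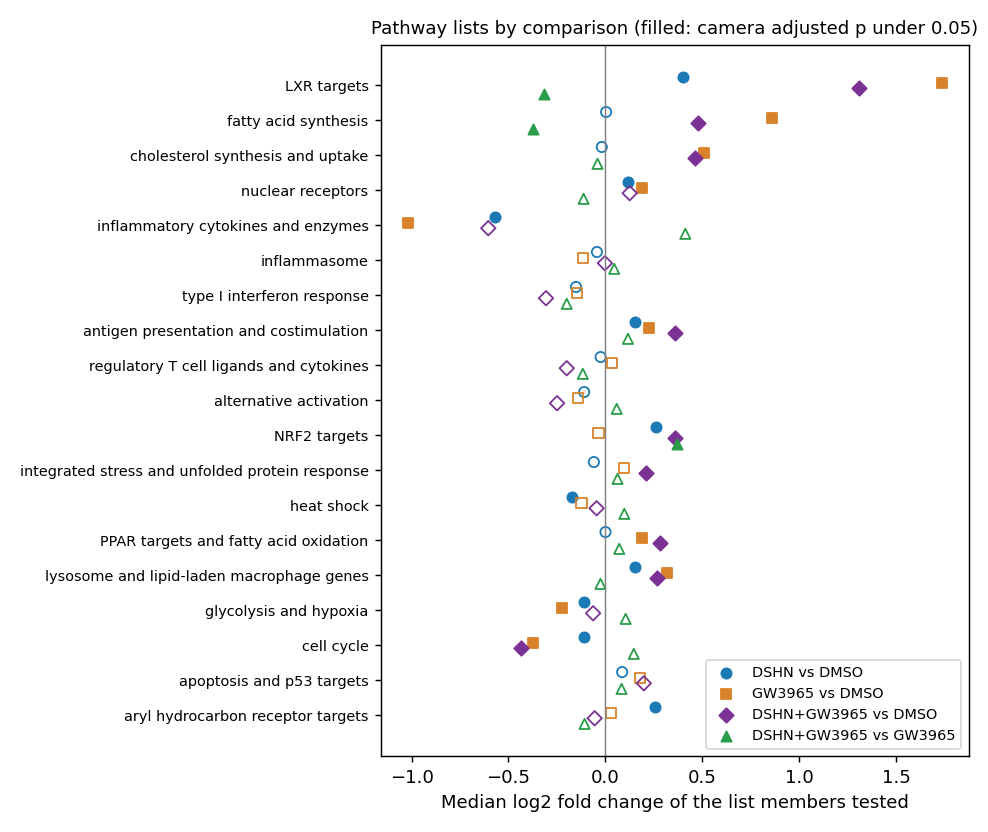
Median log2 fold change (horizontal axis) of the tested members of 19 pathway lists (vertical axis) in 4 comparisons, with filled symbols where camera gave an adjusted p under 0.05. LXR targets had medians of 1.737 with GW3965, 1.308 with both compounds and 0.4 with DSHN against DMSO, and of −0.318 with both against GW3965 alone.

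**Figure D4:**
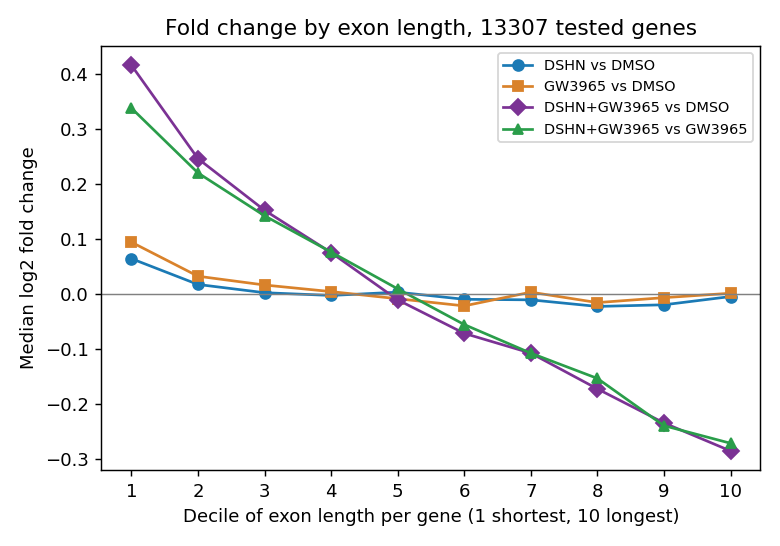
Median log2 fold change (vertical axis) in each decile of exon length (horizontal axis, 1 shortest and 10 longest) for 13307 genes in 4 comparisons. Against GW3965, the combination went from 0.338 in the shortest decile to −0.272 in the longest, while DSHN alone stayed between −0.023 and 0.064.

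The combination against DSHN alone gives the LXR agonist response in the presence of DSHN. LXR targets were higher in 15 of 16 and lower in 1, with Abcg1 at 2.98 (SE 0.10), Abca1 at 2.12 (SE 0.12), Mylip at 1.78 and Srebf1 at 1.77. Fatty acid synthesis genes were higher in 11 of 17 and lower in 1 (12 and 1 adjusted over the list alone), with Scd2 at 3.37, Scd1 at 3.09, Fads2 at 2.08 and Acsl3 at 1.53. Cholesterol genes were higher in 23 of 25 (24 adjusted over the list alone), with Fdps at 1.12, Insig1 at 0.90 and Cyp51 at 0.74. Cd38 was higher by 2.56. The largest falls were in Elk4 (−1.81), Xylt1 (−1.64), Col12a1 (−1.62), Svep1 (−1.49), Tram2 (−1.47) and Usp9x (−1.46), and the cystine transporter gene Slc7a11 had −1.02. They too are given before the length correction, and the longest decile of exon length had a median of −0.273. Cell cycle genes were lower in 13 of 25 and higher in 5, with Mki67 at −0.62. Here 7732 genes changed, 3805 higher and 3927 lower (4048 and 3663 scaled by total counts alone), and 6179 with the length correction, of which 4805 (62.14% of the 7732) kept call and sign and 129 were called with the opposite sign. Of 8 lists called, cholesterol (2.77e-12, and 0.00521) and fatty acid synthesis (4.25e-06, and 0.018) passed with an estimated correlation. LXR targets had 5.34e-12 (adjusted p = 0.0619 with an estimated correlation, 0.0405 with the length correction as well), cell cycle genes 0.0139 (adjusted p = 0.743 with an estimated correlation) and stromal markers, all 9 lower, 0.0102 (adjusted p = 0.675 with an estimated correlation). With the length correction 6 of these 9 were lower, and the median went from −0.40 to −0.22 (0.0164, and adjusted p = 0.684 with an estimated correlation). The calls on the integrated stress response (16 of 22 higher, 2 lower; 0.00149), PPAR targets (11 of 18 higher, 3 lower, 12 and 3 adjusted over the list alone; 0.0102) and antigen presentation (12 of 16 higher; 0.0141) ended with the length correction, at 0.115, 0.118 and 0.625. With an estimated correlation these lists had adjusted p = 0.201, 0.201 and 0.675.

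The interaction asks whether DSHN acts differently with GW3965 present. It was positive for genes that each compound lowered alone: Fos (2.47, SE 0.15), Ccl7 (2.31), Rgs1 (2.26), Ccl2 (2.18), Serpinb2 (2.16) and Cxcl2 (2.10). Fos, for instance, had 54.89 CPM ± 9.216 with DMSO, 14.32 ± 0.8339 with DSHN, 9.624 ± 1.308 with GW3965 and 14.01 ± 1.784 with both. It was negative for Lbp (−2.13), Svep1 (−2.02), Gprin3 (−2.02), Col12a1 (−1.89), Abca1 (−1.80, SE 0.17) and the matrix proteoglycan gene Ogn (−1.70). All of these are values before the length correction, and the longest decile of exon length had a median interaction of −0.273. LXR targets had 12 of 16 negative and 2 positive, with Cd5l at −1.31, Abcg1 at −1.04 and Mylip at −0.78 against Lpl at 0.84. Fatty acid synthesis genes had 10 of 17 negative, with Scd1 at −1.27, Fasn at −1.13 and Acaca at −0.84. Inflammatory genes had 8 of 14 positive and 1 negative, with Tnf at 1.61 and Ptgs2 at 1.19, and cell cycle genes 16 of 25 positive and 5 negative, with Pcna at 0.75. Arg1 had an interaction of 3.86. The test called 6681 genes, 3154 positive and 3527 negative (5877 with the length correction, 22 of them called with opposite signs before and after), and scaling by total counts alone gave 4069 positive and 2853 negative. Camera called 8 lists, none with an estimated correlation: LXR targets (6.88e-05), fatty acid synthesis (0.00242), glycolysis (13 of 22 positive, 3 negative), cell cycle and stromal markers (7 of 9 negative; 0.00391 each), heat shock (8 of 13 positive, 1 negative; 0.0157), nuclear receptors (10 of 16 negative, 3 positive, 11 and 3 adjusted over the list alone; 0.0177) and inflammatory genes (0.0191). With an estimated correlation these had, in the same order, adjusted p = 0.502, 0.291, 0.538, 0.568, 0.538, 0.502, 0.502 and 0.538. The length correction ended the calls of heat shock (0.0601) and inflammatory genes (0.0833). It gained those of lysosome genes (15 of 25 negative before and 16 after; 0.111 before and 0.0148 after) and macrophage identity genes (7 of 18 negative before and 10 after; 0.653 before and 0.0383 after), both with adjusted p = 0.623 with an estimated correlation.

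Across genes, which are not independent replicates, the DSHN effect without GW3965 and the DSHN effect with it had Pearson's r of 0.006 (jackknife SE over libraries 0.155, covariance 6e-04). Of 2431 genes called in both, 1298 moved the same way and 1133 opposite ways. The GW3965 effect without and with DSHN had r of 0.32 (SE 0.093, covariance 0.0482), and of 3937 genes called in both, 2685 moved the same way. The effects of the compounds alone, each against the same 5 DMSO libraries, had r of 0.74 (covariance 0.0741). Simulated groups without any change, set against 5 shared control libraries, gave a mean r of 0.493 with a covariance of 0.0091. No gene was called in both there, but with no change simulated this was all but fixed in advance. It does not measure how far the calls of unrelated effects would overlap. With the DMSO libraries parted between the comparisons (replicates 1 to 3 for one, 4 and 5 for the other), r was 0.584 and the covariance 0.058, against 0.068 from all 5 by the same measure. Of the genes called for DSHN, 3258 (84.6%) were called the same way for GW3965, 1589 higher and 1669 lower. Independent calls of these numbers would give 443.1 and 453.2, but the shared DMSO libraries make the calls dependent. Only 61 genes were called in opposite directions, and Lpl, at −0.96 with DSHN, was higher with GW3965 at 6595 CPM ± 398.3 against 5341 CPM ± 171.8.

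Of 25 interferon response genes, DSHN lowered 2 (none adjusted over the list alone), GW3965 raised 2 and lowered 2 (1 and 0 adjusted over the list alone), and the combination lowered 11 and raised 1 (10 and 1 adjusted over the list alone), with Ifih1 at −0.72 and a list median of −0.31 (camera adjusted p = 0.307, 0.533 and 0.245). Inflammasome genes had 2 of 14 higher and 3 lower with DSHN, 3 and 7 with GW3965 and 5 and 4 with both (0.549, 0.382 and 0.925). Alternative activation genes had 3 of 13 higher and 5 lower with DSHN, 3 and 6 with GW3965 and 2 and 7 with both (0.549, 0.224 and 0.407), with the mannose receptor gene Mrc1 at 0.47 with DSHN. Ligands and cytokines that act on regulatory T cells, a cell type named in the series title, had 2 of 15 higher and 3 lower with DSHN, 5 and 3 with GW3965 and 4 and 6 with both (0.85, 0.86 and 0.474). In that list Entpd1, an ATP-degrading ectoenzyme gene, was at 0.47 with DSHN and 0.81 with GW3965, and Icosl at −0.38 and −0.68. The macrophage markers Lyz2 (10260 CPM ± 276.8 with DMSO), Csf1r (1826 ± 94.26) and Adgre1 (1727 ± 119.8) were high, and macrophage identity genes were higher in 11 of 18 and lower in 3 with GW3965 (12 and 3 adjusted over the list alone, 0.0202, and adjusted p = 0.311 with an estimated correlation). In that list Cx3cr1, which encodes the fractalkine receptor and was picked after its values were seen, went from 374.5 CPM ± 19.2 with DMSO to 184.9 ± 13.82 with DSHN and 120 ± 12.05 with GW3965.

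Markers of other cells, stromal cells apart, were mostly at the floor. The highest neutrophil marker, S100a8, had 0.8142 CPM with DMSO, the highest erythroid marker, Alas2, 0.1787 CPM, and the highest mast cell and basophil marker, Mcpt8, 3.289 CPM. The highest markers of T and NK cells, monocytes, B cells, dendritic cells and megakaryocytes were Cd4 at 8.033 CPM, Vcan at 26.24 CPM, Ighm at 32.12 CPM, Itgax at 81.35 CPM and Pf4 at 152.7 CPM, and the camera lists among these were called in no comparison. Stromal genes were present in every group, with Col1a1 at 1327 CPM in DMSO, 1382 in DSHN, 1547 in GW3965 and 1171 in the combination. With DMSO, Col1a2 had 1047 CPM, Acta2 833.4 and Sparc 599.7, while Dcn (0.2348 CPM) and Lum (0 CPM) of the same list were at the floor. The nuclear RNAs used as signs of RNA quality, Malat1 and Neat1, were both called higher in the combination than in each other group, with a median log2 fold change of 0.81 against GW3965.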

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

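Every test on the 3 patterns below was chosen after its pattern had been seen, and the tests of genomic span, of the length correction and of equal reduction also after the values they rest on.

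Among 196 sets of 5 libraries (44 genes and 5 library measures), 13 held 1 library far from the other 4 by Dixon's ratio over 0.71, where chance gives about 1 in 20 sets. In the combination these were Serpinb2 at 2.214 CPM in replicate 4 (others 1.127 to 1.368), Abca1 at 1131 CPM in replicate 4 (1252 to 1295), Scd1 at 88.11 CPM in replicate 4 (113.6 to 122.9), Nptx1 at 3.188 CPM in replicate 1 (1.881 to 2.214) and Cd38 at 28.79 CPM in replicate 1 (35.06 to 37.32). With DSHN they were Scd1 at 11.2 CPM (13.37 to 14.1) and Rgs1 at 39.91 CPM (29.72 to 31.93) in replicate 1 and Gprin3 at 6.045 CPM in replicate 4 (3.842 to 4.394). With GW3965 they were Il18bp at 49.32 CPM (43.64 to 44.96), Xylt1 at 20.05 CPM (12.43 to 14.62) and Npy at 13.76 CPM (10.81 to 11.64) in replicate 1 and Dhrs9 at 6.306 CPM in replicate 4 (4.359 to 4.887). With DMSO it was Neat1 at 87.58 CPM in replicate 4 (104.7 to 110.1). The DSHN effect differed with and without GW3965 in 6681 genes by the interaction test, and 1133 genes were called in both settings with opposite directions. Mitochondrial rRNA and tRNA features took 0.2318% of counts in the combination against 0.1233% with DMSO.

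Splits of the libraries into other groups of the same sizes argue against chance for the gene counts of the 5 pairwise contrasts. For the interaction they cannot decide, since all 20 libraries were regrouped there, which also breaks up the effects of the compounds alone. In each of the 6 contrasts only 1 of 100 splits, the real one, called as many genes: 3852 for DSHN (highest other 901), 6194 for GW3965 (3727), 8629 for the combination against DMSO (4579), 7688 against GW3965 (4460), 7732 against DSHN (4732) and 6681 for the interaction (5702). Chance cannot be excluded by these splits for the numbers of lists called by camera. Nor do the splits speak for chance, since a regrouping can still hold part of the treatment effects. As many lists were called by 5 of 100 splits for DSHN (10 lists, highest other 11), 25 for GW3965 (11 lists, 15), 25 for the combination against DMSO (9 lists, 12), 55 against GW3965 (4 lists, 10), 24 against DSHN (8 lists, 11) and 31 for the interaction (8 lists, 11).

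Genes with a long summed exon length were lower and genes with a short one higher in the 5 combination libraries than in the other 15. Depth is argued against, since with every library thinned to 16855029 counts the difference of the slopes was −0.1502 (SE 0.0073) against −0.1508 before; an earlier test, that 2 of 5 combination totals lay within the range of the others, decided nothing and was replaced. The coefficient of genomic span at like exon length and GC content was −0.0482 (SE 0.002), and −0.0398 (SE 0.0018) with transcript length in place of both. It cannot decide on fragmentation by transcript length alone, since neither length need be that of the transcripts present in these cells. Fragmentation alone therefore stays open. Transcription through long gene bodies alone stays open too. In 572 genes without introns the slope on exon length was −0.0725, below the coefficient of genomic span by −0.0243 (SE 0.0111). That error takes genes as independent, and the slope, unlike the coefficient, was not adjusted for GC content. In the regression with exon length, genomic span and GC content, exon length had −0.1132 (SE 0.0033), where span alone would give 0. These values show that annotated span does not hold the whole trend. They cannot decide on transcription, since the annotated span need not be the stretch transcribed in these cells (GC content as a cause is not weighed here). A mixture of these, an effect of the 2 compounds together, and handling of the 5 combination cultures or libraries as 1 set all stay open, since the labels give no batch and the group is the set.

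LXR target genes were lower in the combination than with GW3965 alone, at a median of −0.318, a list call with adjusted p = 0.912 with an estimated correlation. The length trend as the whole cause is argued against by a median of −0.321 after its removal, and scaling by medians of −0.262 under total counts and −0.319 under RLE factors. An equal reduction of every GW3965 response stays open at the level of list medians. The ratio compared was that of the combination effect against DMSO to the GW3965 effect. Its median was 0.751 in 15 LXR targets, 0.755 in 16 fatty acid synthesis genes and 1.008 in 23 cholesterol genes. LXR minus cholesterol was −0.257 (jackknife SE over libraries 0.072), but the permutation p adjusted over 6 tests was 0.124. Ratios of single genes, themselves not tested, ran from 0.065 to 1.122, −1.161 to 1.933 and 0.215 to 1.55 in the same order. The gene test of the combination against GW3965 did cover each gene. Of 25 cholesterol genes, 23 of them raised by GW3965 alone, it called 7 higher and 7 lower (6 and 7 after the length correction). An equal reduction would leave no raised gene higher, so as the only cause in every single gene it is argued against. An earlier form of the ratio, the combination against DSHN over the GW3965 effect (difference −0.437, adjusted permutation p = 0.0492), was set aside since it also falls where DSHN alone raises a gene, as in these LXR targets (median 0.455, against −0.011 in the cholesterol genes). The form kept can in turn be raised by that rise, so neither form is free of the effect of DSHN alone. Inhibition of LXR by NR0B2, as the series proposes, was not tested and stays open, as does handling of the combination group as a set; with DSHN alone 10 of 16 LXR targets were higher, and Nr0b2 RNA, at 0 to 8 counts per library, was lower by a test chosen after its counts were seen (exact adjusted p = 0.0397) but not called in the fit without a filter (adjusted p = 0.129).

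Of 1669 genes lower with each compound alone, 976 (58.5%) had a positive interaction past the threshold and so were less low with both than the 2 effects added, with a median interaction of 0.479 and median log2 fold changes against DMSO of −0.29 (DSHN), −0.412 (GW3965) and −0.25 (both). A floor of expression is argued against by their median of 28.41 CPM with GW3965, and a single high DMSO library by a median interaction of at least 0.456 whichever DMSO library was left out. The DMSO libraries standing apart from all treated ones stays open: 33.8% of the genes were called between GW3965 and DSHN, but so were 17.1% of all genes, so the bar of 5% set for this test decided nothing, and such a shift can add to a difference between the compounds. Also open is a shared response that both compounds together do not add to. These genes were picked by that interaction, so its median is no evidence for the pattern.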

How the results depend on the processing

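The length corrections and the exact test of Nr0b2 were chosen after seeing the data; the other alternatives were fixed before. Counts of called genes stayed within 1.5 times under every alternative except glmTreat against a fold of 1.5, which by construction asks for larger changes: 61 (DSHN), 322 (GW3965), 857 (combination against DMSO), 249 (against GW3965), 300 (against DSHN), 334 (interaction) and 44 shared by the compounds. Leaving out 1 library gave 3159 to 3885, 5674 to 6215, 8256 to 8472, 7198 to 7696, 7195 to 7652 and 6281 to 6834 genes in the same order, and 2670 to 3333 shared. Equal replicate numbers were tested as pairs by correlating residuals of libraries of different groups: 10 of 30 pairs had r over 0.1 (range −0.205 to 0.247). Mean r was 0.124 for DMSO and GW3965, 0.096 for DMSO and the combination and 0.129 for GW3965 and the combination (6, 8 and 7 of 10 libraries correlated best with their own number), but −0.064, −0.098 and −0.065 for DSHN with DMSO, GW3965 and the combination (2, 0 and 1 of 10). A replicate block gave 3988, 6272, 8640, 7817, 7794 and 6771, and the correction for length, span and GC content 4147, 6489, 7762, 6292, 6129 and 5925. Total counts only moved the median of all genes by at most 0.074, yet changed the split of calls by direction. Camera with an estimated correlation called 1, 3, 3, 1, 2 and 0 lists in the same order (the cause was not tested). Fry, which does not compare a list with other genes, called 21 for GW3965, 20, 11 and 19 for the combination against DMSO, GW3965 and DSHN, and 14 for the interaction. The length correction left 5 lists for the combination against DSHN. The correlation of the DSHN effects lies within its error of 0 (SE 0.155) and changes sign, from −0.057 without DSHN replicate 1 to 0.069 without DSHN replicate 5, and is −0.028 with the length correction; that of the GW3965 effects stayed at 0.287 to 0.36. Over 520 named gene results and 11190 alternatives, 454 lost the call (364 under glmTreat, 53 on leaving out 1 library, 24 with the length correction), 2 gained it and 7 reversed. The reversals came with the length correction, which moves short and long genes apart by construction, and none passed the threshold: against GW3965 Nr3c1 0.010, H2-DMb1 −0.035, H2-D1 −0.028 and Il4ra 0.016, and against DSHN Ctss −0.015, Hspa4l 0.029 and Pfkfb3 0.000. Depth limits Nr0b2, at 0 to 8 counts per library: DSHN against DMSO passed an exact permutation test (adjusted p = 0.0397) and missed the threshold in the fit without a filter (adjusted p = 0.129).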

Other observations

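The genes below were chosen after their values were seen, and no list of them was tested. Dbp, a clock-controlled transcription factor gene, had log2 fold changes against DMSO of 1.34 with DSHN, 1.29 with GW3965 and 1.34 with both, and Nr1d2, which encodes a clock repressor, had 0.61, 0.70 and 0.62. Per3 (0.76, 0.67 and 0.36), Tef (0.40, 0.55 and 0.23) and Nr1d1 (0.47, 0.59 and 0.24) passed in all 3 comparisons. The core activator genes Arntl and Clock had −0.04 and −0.07 with DSHN and −0.05 and −0.05 with GW3965, none called, and −0.30 and −0.38 with both, both called. With the length correction Arntl was no longer called in the combination (adjusted p = 0.248). The metallothionein genes Mt1 and Mt2, whose products bind zinc and copper, rose by 0.52 and 0.53 with DSHN, 0.72 and 0.86 with GW3965 and 1.16 and 1.20 with both.

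In the combination against GW3965 alone, Hspg2 had a log2 fold change of −1.52, Col6a3 −1.37, Fn1 −1.37, Col3a1 −0.60, Col1a1 −0.40 and Sparc −0.18. The last 3 belong to the stromal cell marker list, whose 9 tested members were all lower here. The 6 genes remained called with the length correction, at −1.25, −1.10, −1.13, −0.46, −0.24 and −0.26. In the same comparison Kcnq1ot1 was at 0.81 and Clk4, which encodes a kinase of splicing factors, at 0.62. Neat1 (1.06) and Malat1 (0.55), the RNAs of the RNA quality list, were higher too.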
